A study of Mus musculus with 5 samples.

How the data were processed

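RNA from the kidney of NZB/NZW F1 mice treated with diosmetin (50 mg/kg every other day for 6 weeks, 3 libraries) or vehicle (2 libraries) was analysed from a single deposited table of FPKM values, with a column per library. Per the labels' protocols, total RNA that met an integrity minimum was depleted of ribosomal RNA, made into stranded libraries and sequenced as paired ends. The authors' FPKM values are scaled to transcript length and to each library's total, and no further scaling between libraries is recorded. The genome build was GRCm38 per the submitters' processing notes. The aligner, the counter, the annotation release and whether counting used strand are not given in the sources used here, so antisense and overlapping genes and close paralogs cannot be separated with certainty. Each column was matched to its sample by the sample code in the labels, and groups were taken from the treatment label.

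The table held 21878 genes, and 21723 of them (99.3%) were matched by GeneID to the mouse RefSeq gene table of assembly GRCm38.p6, from which chromosome, start and end were taken as whole gene spans. Of the genes matched, 21402 were protein-coding. None of the 13 mitochondrially encoded genes in the fixed lists was used here. No library held values identical to another.

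Depth was recovered from the values, because the lowest FPKM values of a library step by whole fragments. Of 1096 genes with a mean FPKM under 0.05, 969 (88.4%) took values that were whole multiples of 1 step within 2% and at most 0.1 fragments. Step sizes of 475 of these genes, with transcript lengths from GENCODE, gave absolute depths. Their middle range was 38.1 to 42.5 M fragments for vehicle replicate 1, 48.2 to 53.8 for vehicle replicate 2, 46.5 to 51.9, 42.7 to 47.6 and 44.8 to 50.0 for diosmetin replicates 1, 2 and 3. These are estimates, and no count test was run on them.

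Values were taken as log2(FPKM + 1), a scale that understates the change of low genes. The 13290 genes with a mean FPKM of at least 0.5 over all 5 libraries were tested with limma (lmFit and eBayes with a mean-variance trend, 3 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment at 0.05. Differences are diosmetin minus vehicle. Gene lists (33, covering interferon, lipid, injury and cell type genes) were fixed before the data were examined, and the 28 with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. Some genes stand in more than 1 list. List scores, the mean log2 value of a list in a library, were compared by an exact permutation test over the 10 splits of the 5 libraries, whose smallest p is 0.1.

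The genes named follow a rule written before the data were examined. It takes up to 12 genes per direction with the largest fold among those that pass, with a mean FPKM of at least 1, no overlap between groups and a standard symbol, and fills each direction to 8 by the smallest unadjusted p where too few pass. Since none passed, both directions were filled in this way. It adds up to 3 members of each list with the largest log2 difference, or up to 4 that pass, and 18 genes named in advance. Genes outside the rule, such as Samd9l, Ddx58, Scnn1b and Aqp2, were named after their values were seen. A few genes that the rule names are not reported here and are left out of the counts of named genes, while the list tests keep them.

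The procedure was tested on simulated data, with 20 simulations of the diosmetin and vehicle libraries over 13290 genes and independent noise between genes. Gene variances were drawn from the prior that limma fitted, after an earlier version with the moderated variances, which are shrunk, had given a higher recovery. Of genes given a log2 change of 0.5, 22.4% were called, as were 78.8% at 1 and 97.5% at 2, with 7.3 false calls per simulation. A shift of -0.25 put on the interferon-stimulated list was called in 20 of 20 simulations. The simulations hold no difference shared by many genes of a library, so the recovery is an upper estimate. For the same reason they cannot show how often a list is called falsely in these data. The estimated correlation of the interferon-stimulated list in the data was 0.82.

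Alternatives planned in advance were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 1, median-of-ratios scaling, rescaling to TPM, quantile normalization, no variance trend, array quality weights and leaving out each library in turn. The number of genes at an unadjusted p under 0.05, the numbers of collecting duct and T and NK cell members that pass adjusted over the list alone, a test of KEGG pathways from the deposited annotation, and leaving out each library in those pathways and in the differences between marker groups were added after the data were seen. R 4.3.3, limma 3.58.1, data.table (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.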

Results

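Kidney RNA was profiled in NZB/NZW F1 mice, a hybrid between inbred strains that spontaneously develops lupus-like autoimmunity and nephritis. Mice had received diosmetin, a plant flavone, at 50 mg/kg by injection into the peritoneal cavity every other day for 6 weeks, or vehicle. There were 3 diosmetin libraries and 2 vehicle libraries, each made from ribosomal RNA-depleted total RNA and sequenced as paired ends. Expression was given as FPKM (fragment counts scaled to transcript length and library total) for 21878 genes, of which 3733 were listed at 0 in every library. Depth, estimated from the step size of the lowest values, was 38.4 and 48.6 M fragments in vehicle replicates 1 and 2, and 46.9, 43.0 and 45.1 M in diosmetin replicates 1, 2 and 3. At those depths an FPKM of 1 in a 2 kb transcript rested on 76.8 to 97.2 fragments. Between 12028 and 12393 genes per library had an FPKM of at least 1. Pearson correlations of log2 values across genes ranged from 0.992 to 0.997 between libraries (genes are not independent replicates), and the lowest value belonged to the vehicle pair. Nothing in the labels says that the libraries came from separate animals, so the p-values measure the spread between these samples, which may be technical.

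The first comparison asked which kidney genes differed between diosmetin and vehicle. The genes with the smallest p-values among those higher under diosmetin were mostly genes of the acid-base transporting intercalated cells of the collecting duct. Atp6v0d2, a subunit of the vacuolar proton pump, stood at 19.9 ± 0.723 FPKM (SD, n = 3) under diosmetin and 13.2 ± 0.855 (SD, n = 2) under vehicle, a log2 difference of 0.56 ± 0.07 (SE). Apoe, which encodes the lipid-carrying apolipoprotein E, was at 245 ± 39.1 against 125 ± 9.86 FPKM, and Tff3, a secreted trefoil peptide, was at 3.88 ± 0.811 against 1.23 ± 0.045 FPKM. In the other direction, Ttr, the thyroid hormone and retinol carrier transthyretin, was at 11.7 ± 2.04 under diosmetin against 41.7 ± 17.5 FPKM under vehicle, and Ces1f, a carboxylesterase, was at 13.7 ± 1.90 against 24.6 ± 1.41 FPKM. None of these differences passed the test over all genes.

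With limma, 0 of 13290 genes changed at an adjusted p of 0.05, and the smallest adjusted p was 0.738. At an unadjusted p under 0.05 there were 847 genes, 622 higher and 225 lower, where 664 would be expected by chance. That number was 386 without diosmetin replicate 2 and 1463 without vehicle replicate 2. Of the genes at that level 73.4% were higher as deposited, 50.5% with each library rescaled by the median of ratios, and 33.2% without vehicle replicate 1. The groups did not overlap for 3253 genes, which is 24.5% of those tested, where chance gives 20%. Of these, 2433 were higher and 820 lower. The median log2 difference over all tested genes was 0.04, and 18 genes differed by more than 1 on the log2 scale. Of the 28 gene lists tested 8 passed camera with a preset correlation and 0 with an estimated one. In the 9 other splits of the 5 libraries into groups of 3 and 2, between 5 and 13 lists passed with the preset correlation, and 7 of these splits gave at least 8.

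The 8 genes named for the smallest p-values in the higher direction were Atp6v0d2, Tff3, Slc4a1, Atp6v1c2, Apoe, Aqp6, Slc26a4 and Foxi1, and their log2 differences lay between 0.40 and 1.12. By the mouse RefSeq annotation of GRCm38, Atp6v0d2 (GeneID 242341) lies on chromosome 4 from 19876838 to 19922566, Apoe (GeneID 11816) on chromosome 7 from 19696244 to 19701310, and Tff3 (GeneID 21786) on chromosome 17 from 31125306 to 31129611. In the lower direction the 8 genes were Ces1f, Angptl7, Ttr, Slc16a4, Tyw3, Fam229b, Cacna2d2 and Ugt3a1, with log2 differences from -1.69 to -0.43. Ttr (GeneID 22139) lies on chromosome 18 from 20664209 to 20674326 and Ces1f (GeneID 234564) on chromosome 8 from 93256236 to 93279766. Angptl7, a secreted angiopoietin-like protein, was at 65.7 ± 4.68 FPKM under diosmetin and 96.8 ± 5.62 under vehicle. Slc16a4, a member of the monocarboxylate transporter family, was at 42.7 ± 1.60 against 57.9 ± 3.50 FPKM, and Ugt3a1, a glycosyltransferase, at 74.5 ± 7.05 against 104.0 ± 7.57 FPKM.

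The design asks about type I interferon signalling in the kidney, and interferon-stimulated genes were high in 1 of the 2 vehicle libraries. Ifit1, an interferon-induced protein that binds viral RNA, was at 1.71 FPKM in vehicle replicate 1, 5.0 in vehicle replicate 2, and 2.01, 1.85 and 1.92 in the diosmetin libraries. Isg15, a ubiquitin-like modifier, was at 1.38 and 4.36 FPKM under vehicle and at 1.21, 1.02 and 1.79 under diosmetin. Irf7, the transcription factor that amplifies interferon production, was at 2.82 and 13.3 FPKM under vehicle and at 4.88, 4.91 and 4.18 under diosmetin. Oas2 was at 0.779 and 1.72 FPKM under vehicle and 1.18 ± 0.054 (SD, n = 3) under diosmetin, and Ifnar1, a chain of the type I interferon receptor, at 11.5 ± 0.943 (n = 2) and 11.2 ± 0.270 (n = 3).

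Over the 48 measured interferon-stimulated genes, 45 had a lower mean under diosmetin and 3 a higher one, and the mean log2 difference was -0.21. No member passed over all genes, and 0 passed adjusted over the list alone. Samd9l alone had an unadjusted p under 0.05, at 29.2, 26.4 and 28.3 FPKM under diosmetin against 32.9 and 34.0 under vehicle. The groups did not overlap for 2 of the 48 genes, Samd9l and Ddx58, which encodes the RNA sensor RIG-I, against 24.5% of all tested genes. Against all other genes the list was lower (adjusted p = 4.18e-09, camera with a preset correlation), while adjusted p = 0.90 with an estimated correlation. The list score did not differ by the exact permutation test (p = 0.7, two-sided), whose smallest possible p is 0.1. Without vehicle replicate 2 the mean turned to 0.17 (adjusted p = 0.035, camera), and without vehicle replicate 1 it was -0.58 (adjusted p = 7.15e-44), in a range of adjusted p over all alternatives that keep the preset correlation from 7.15e-44 to 0.035. Ifit3 and Ifit3b, and the Oas1 genes, are close paralogs whose fragments the counting could have divided, and Mx1 is not analysed here.

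**Figure D1:**
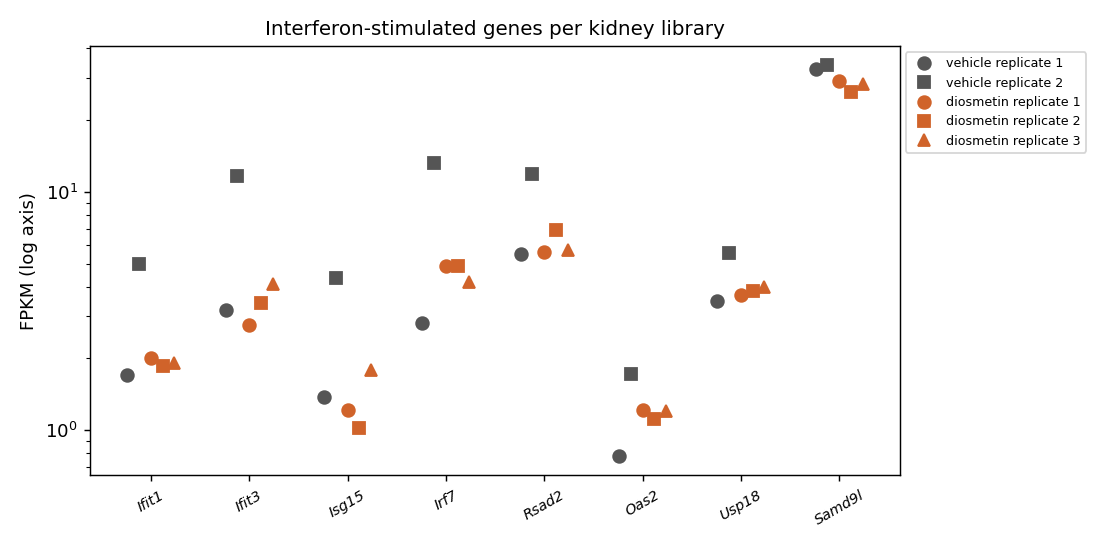
FPKM, on a log axis, of 8 interferon-stimulated genes in each kidney library, with 1 point per library, grey for vehicle and orange for diosmetin. Vehicle replicate 2 is the highest library for each gene (Irf7 at 13.3 against 2.82 to 4.91 FPKM in the others), and both vehicle libraries lie above diosmetin for Samd9l.

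Several other interferon and inflammation genes were highest in the same vehicle library. Cxcl10, a T cell-attracting chemokine induced by interferons, was at 1.16 and 6.84 FPKM under vehicle and at 1.71 ± 0.600 (SD, n = 3) under diosmetin. Tnf was at 0.189 and 1.84 FPKM under vehicle and 0.228 ± 0.217 under diosmetin, and Vcam1, an adhesion molecule for leukocytes, at 3.60 and 12.5 against 4.76 ± 0.273. Complement C3 was at 7.62 and 19.9 FPKM under vehicle and at 8.91 ± 1.53 under diosmetin. Socs1, an inhibitor of cytokine signalling, went the other way at low levels, with 0.707 ± 0.173 FPKM under diosmetin and 0.243 ± 0.069 under vehicle.

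The 23 interferon gamma-induced genes were lower as a list (mean log2 difference -0.13, adjusted p = 0.00299, camera with a preset correlation), with 20 members lower and 3 higher, while adjusted p = 0.90 with an estimated correlation. Without vehicle replicate 2 this mean was 0.22 (adjusted p = 0.034), and without vehicle replicate 1 it was -0.49. Neither the 18 genes of interferon production and reception (mean -0.04, adjusted p = 0.32) nor the 23 of MHC and antigen presentation (0.10, adjusted p = 0.66) passed. The 16 measured cytokines and chemokines (-0.13, adjusted p = 0.074) and the 13 complement genes (0.0024, adjusted p = 0.15) did not pass either. For complement the camera direction was lower although the mean lay just above 0, because the test sets a list against all other genes. Without vehicle replicate 1 the means were -0.19 for production and reception (adjusted p = 0.00124), -0.23 for MHC and antigen presentation (4.35e-09), -0.48 for cytokines and chemokines (8.63e-07) and -0.08 for complement, and without vehicle replicate 2 they were 0.11, 0.43 (adjusted p = 8.19e-11), 0.21 and 0.08. The complement mean was also below 0 without diosmetin replicate 2 (-0.05) or 3 (-0.04). In these lists no member passed over all genes, and none passed adjusted over the list alone. At an unadjusted p under 0.05 stood Socs1 and Mavs, the mitochondrial adaptor of RNA sensing, both higher.

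The study's title adds phosphatidylethanolamine metabolism, and transcripts of its main synthetic enzymes lay close together in the groups. Pcyt2, the rate-limiting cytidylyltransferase of the ethanolamine pathway, was at 58.1 ± 2.54 FPKM (SD, n = 3) under diosmetin and 55.8 ± 5.32 (SD, n = 2) under vehicle. Etnk1, an ethanolamine kinase, was at 84.8 ± 3.56 against 83.2 ± 2.74 FPKM, and Pisd, the mitochondrial phosphatidylserine decarboxylase, at 18.0 ± 0.464 against 18.3 ± 2.32. Etnk2 was at 3.07 ± 0.703 against 2.99 ± 0.296 FPKM. Etnppl, which breaks down phosphoethanolamine, was at 2.59, 2.59 and 3.42 FPKM under diosmetin and 4.92 and 4.38 under vehicle, a log2 difference of -0.55 ± 0.13 (SE). Pemt, which methylates phosphatidylethanolamine to phosphatidylcholine, was at 0.712 ± 0.046 against 0.412 ± 0.004 FPKM.

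Of the 25 measured genes of this list 17 were higher and 8 lower, with a mean log2 difference of 0.04 (adjusted p = 0.85, camera). The list score did not differ by the exact permutation test (p = 0.5, two-sided, smallest possible 0.1). Etnppl was the only member at an unadjusted p under 0.05, and 0 passed over all genes by limma or adjusted over the list alone. The groups did not overlap for 6 of the 25 members, about the share among all tested genes (24.5%). The mean turned to -0.0068 with median-of-ratios scaling and to -0.010 without vehicle replicate 1. Under that scaling Etnk1 and Etnk2 also turned negative, and Pcyt2 did without vehicle replicate 2 (-0.04).

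Lists chosen for actions known of flavones and for renal metabolism did not pass. Cyp1a1, the classical target of the aryl hydrocarbon receptor, was at 1.03, 1.94 and 1.01 FPKM under diosmetin and 0.673 and 0.820 under vehicle, and Cyp1b1 at 6.24 ± 1.21 against 5.80 ± 0.283. The 7 measured targets of that receptor had a mean log2 difference of 0.03 (adjusted p = 0.69, camera, whose direction was lower). Among 15 NRF2 targets, genes of the antioxidant response, the mean was 0.09 (adjusted p = 0.32) and, without vehicle replicate 1, a mean of 0.05, and Srxn1, which reduces peroxiredoxins, was at 19.1 ± 2.83 against 14.6 ± 1.73 FPKM. The 22 genes of fatty acid oxidation and PPAR-alpha had a mean of 0.13 (adjusted p = 0.66). Acot1 was at 51.6 FPKM in vehicle replicate 1 and between 121 and 134 in the other libraries, and it shares sequence with Acot2. The 20 genes of cholesterol synthesis had a mean of 0.11 (adjusted p = 0.47). The fatty acid oxidation mean was -0.12 without vehicle replicate 1 (adjusted p = 0.046), 0.39 without vehicle replicate 2 (6.68e-04) and 0.0056 without diosmetin replicate 1, the cholesterol synthesis mean -0.0028 without vehicle replicate 1, and the receptor target mean -0.07 without vehicle replicate 2. No member of these lists passed over all genes or adjusted over the list alone.

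Markers of the collecting duct were higher under diosmetin. Foxi1, the transcription factor that specifies intercalated cells, was at 26.9 ± 2.45 FPKM (SD, n = 3) against 17 ± 1.44 (SD, n = 2), and Slc26a4, the apical chloride and bicarbonate exchanger pendrin, at 34.2 ± 2.34 against 22.9 ± 2.05. Slc4a1, the basolateral exchanger AE1, was at 28.6 ± 0.179 against 21.5 ± 0.167 FPKM, and Aqp6, an aquaporin of acid-secreting cells, at 45.5 ± 3.19 against 31.7 ± 1.45. In the principal cells, which take up sodium and water, Scnn1b, a subunit of the epithelial sodium channel, was at 32.9, 30.5 and 32.1 FPKM against 25.4 and 27.0. Aqp2, the water channel regulated by vasopressin, differed by 0.16 ± 0.15 (log2, SE).

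Of 19 measured collecting duct markers, 18 had a higher mean, and 14 rose adjusted over the list alone, while 0 passed over all genes by limma. Of those 14, 10 were among the 11 intercalated cell members and 4 among the 8 principal cell members. The groups did not overlap for the same 14 of the 19 markers, against 24.5% of all tested genes. A small p and a lack of overlap come from the same values, so the second adds no separate support. The mean log2 difference of the list was 0.32 (adjusted p = 5.08e-13, camera with a preset correlation), while adjusted p = 0.54 with an estimated correlation (unadjusted p = 0.019). The exact permutation test of the list score gave p = 0.1, the smallest it can give with 10 splits. The number passing adjusted over the list alone was 8 with median-of-ratios scaling, 9 without vehicle replicate 1 and 13 without vehicle replicate 2. Slc4a1 is also made by red cell precursors, and it was the only one of 9 red blood cell markers that passed adjusted over that list alone.

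**Figure D2:**
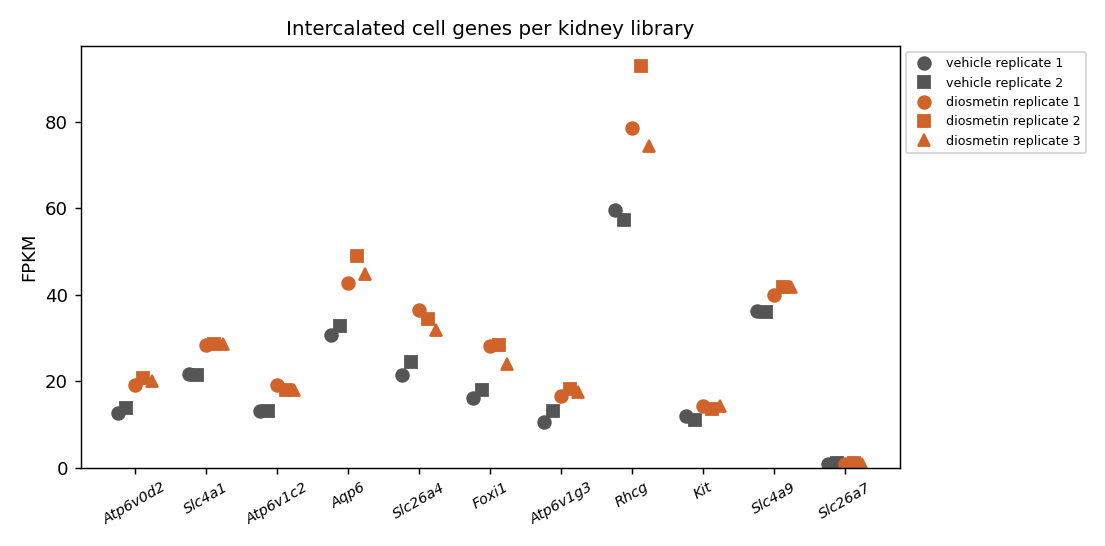
FPKM of the 11 measured intercalated cell genes in each kidney library, with 1 point per library, grey for vehicle and orange for diosmetin. Every diosmetin library lies above both vehicle libraries for 10 of the genes (Foxi1 from 24 to 28.3 against 16 and 18 FPKM), and Slc26a7 overlaps at about 1 FPKM.

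Other nephron segments differed in direction. Umod, the glycoprotein uromodulin of the thick ascending limb, was at 1071, 1781 and 1597 FPKM under diosmetin and 1011 and 1246 under vehicle, and Calb1, the calcium-binding protein of the distal tubule, was at 242 ± 56.2 (SD, n = 3) against 175 ± 27.4 (n = 2). Slc5a2, the glucose transporter SGLT2 of the early proximal tubule, was at 39.0, 13.3 and 24.9 FPKM under diosmetin and 75.7 and 33.0 under vehicle. Kap, an androgen-regulated protein of the proximal tubule, was at 3370 ± 1203 against 5431 ± 1022 FPKM. Cdkn1c, a cell cycle inhibitor expressed in podocytes, was at 15.85 ± 2.36 FPKM under diosmetin and at 11.87 and 30.95 under vehicle.

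Of 18 loop of Henle and distal tubule markers 17 were higher (mean log2 difference 0.22, adjusted p = 3.42e-04, camera with a preset correlation), and of 32 proximal tubule markers 28 were lower (mean -0.30, adjusted p = 1.06e-10). With an estimated correlation the adjusted p was 0.79 for each. The proximal tubule mean was -0.18 without vehicle replicate 1 and -0.42 without vehicle replicate 2, and its centred score overlapped between the groups (0.070 in diosmetin replicate 1, 0.058 in vehicle replicate 2), with p = 0.3 by the exact permutation test. No member of either list passed over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 5 loop and distal markers, all higher, and 4 lower and 1 higher proximal tubule markers. The 18 podocyte markers were lower as a list (mean -0.09, adjusted p = 0.042, adjusted p = 0.90 with an estimated correlation), but 0.18 without vehicle replicate 2 (adjusted p = 0.035) and -0.36 without vehicle replicate 1. The podocyte call was also lost without diosmetin replicate 1 (adjusted p = 0.066) or 3 (0.13), with median-of-ratios scaling (0.076) and with no filter on low values (0.10).

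**Figure D3:**
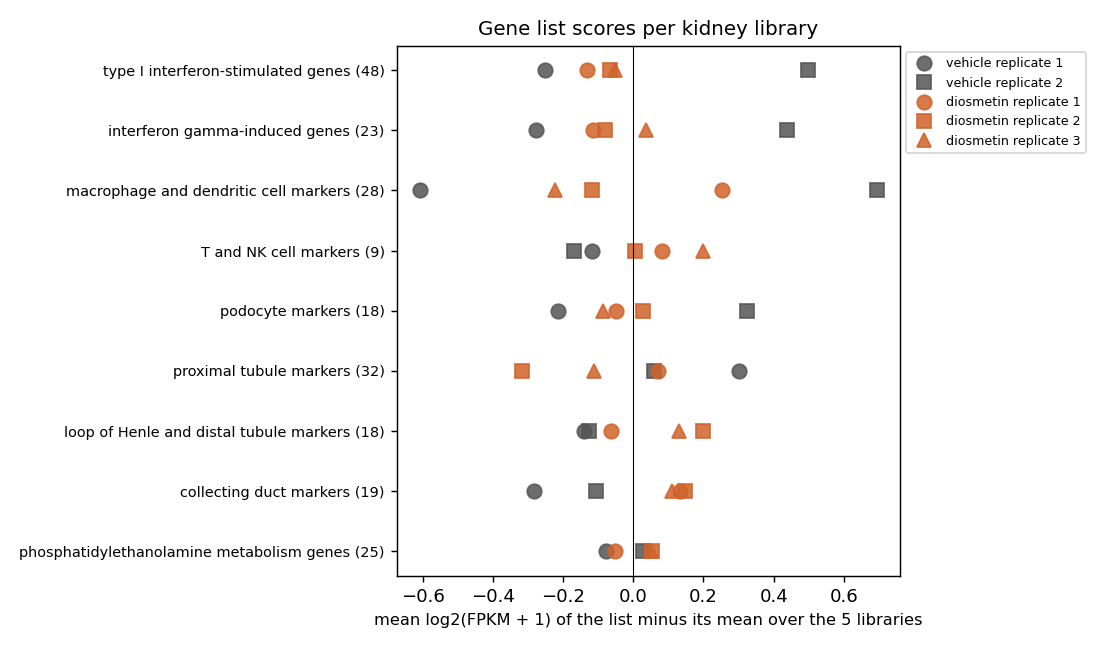
Score of 9 gene lists in each kidney library, as the mean log2(FPKM + 1) of the list's genes minus its mean over the 5 libraries, with the number of genes in parentheses and 1 point per library. Vehicle replicate 2 is the highest for interferon-stimulated genes (0.50) and macrophage markers (0.69), where vehicle replicate 1 is the lowest (-0.25 and -0.61), and both vehicle libraries lie below all diosmetin libraries for collecting duct markers.

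Macrophage and dendritic cell markers differed more between the vehicle libraries (1.30 in the list score) than between the groups. C1qa, a complement component made by macrophages, was at 3.23 FPKM in vehicle replicate 1, 12.7 in vehicle replicate 2 and 9.04 ± 1.51 (SD, n = 3) under diosmetin. Cybb, of the phagocyte oxidase, was at 1.77 and 12.4 FPKM under vehicle and 3.74 ± 2.05 under diosmetin. Gzmb, the granzyme B of cytotoxic lymphocytes, was at 1.82, 2.38 and 2.27 FPKM under diosmetin and 0.937 and 0.276 under vehicle, and Cd8a at 1.52 ± 0.016 against 0.795 ± 0.324. Among B and plasma cell genes, Jchain was at 4.50 ± 1.21 against 3.65 ± 1.0 FPKM.

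The 28 macrophage and dendritic cell markers were lower as a list (mean -0.07, adjusted p = 0.042, camera with a preset correlation, adjusted p = 0.97 with an estimated correlation), yet 0.58 without vehicle replicate 2 (adjusted p = 7.17e-07) and -0.72 without vehicle replicate 1. The mean was -0.21 without diosmetin replicate 1, -0.03 without diosmetin replicate 2 (adjusted p = 0.17) and 0.025 without diosmetin replicate 3 (adjusted p = 0.34), and the call was also lost with a pseudocount of 0.1, no filter on low values, median-of-ratios scaling and quantile normalization. Only 9 of the 37 listed T and NK cell markers reached the filter and were tested. They had a mean of 0.24 (adjusted p = 0.15, camera). All 3 diosmetin scores lay above both vehicle scores, with p = 0.1 by the exact permutation test, its smallest value. The list passed with the preset correlation without vehicle replicate 1 (adjusted p = 0.036) or diosmetin replicate 2 (0.014), while with all libraries adjusted p = 0.79 with an estimated correlation. Gzmb passed adjusted over the list alone (log2 difference 1.0, adjusted p = 0.021) but not over all genes. It no longer did so without diosmetin replicate 2 (adjusted p = 0.11), without diosmetin replicate 3 (0.10), with no filter on low values (0.11) or with quantile normalization (0.056). Cd8a passed as well, for 2 members in all, without vehicle replicate 1, with a mean FPKM of at least 1, no variance trend or array quality weights. Only 6 of the 30 listed B and plasma cell markers reached the filter and were tested. They did not pass as a list (mean -0.02, adjusted p = 0.65, camera), with a mean of -0.27 without vehicle replicate 1 and 0.24 without vehicle replicate 2.

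Injury, matrix, proliferation and vascular genes gave no list that passed with all 5 libraries. Havcr1, the injury marker KIM-1, was at 5.47, 14.4 and 8.84 FPKM under diosmetin and 7.59 and 10.3 under vehicle, and Lcn2 at 1.78, 4.85 and 1.30 against 0.672 and 1.09. Ren1, renin, was at 180 ± 67.3 FPKM under diosmetin and 105 ± 27.2 under vehicle, and Kdr, the endothelial receptor for VEGF, at 21.7 ± 3.02 against 28.1 ± 4.19. The mean log2 difference was 0.13 for 23 kidney injury genes (adjusted p = 0.66), 0.17 for 25 fibrosis and matrix genes (0.65) and 0.11 for 13 cell cycle genes (0.66). It was 0.02 for 19 endothelial markers (adjusted p = 0.41, with the camera direction lower) and 0.12 for 17 mesangial, smooth muscle and fibroblast markers (0.92). Each of these 5 means turned below 0 without vehicle replicate 1, to -0.07 for injury, -0.16 for fibrosis (adjusted p = 0.00443), -0.11 for cell cycle, -0.21 for endothelial (1.79e-05) and -0.08 for mesangial genes, and the endothelial mean did so without diosmetin replicate 2 (-0.07, adjusted p = 0.017). Without vehicle replicate 2 they were 0.33, 0.49 (adjusted p = 1.13e-04), 0.33 (0.012), 0.25 (0.035) and 0.31 (0.040), and fibrosis genes also passed without diosmetin replicate 1 (0.32, adjusted p = 0.020). None of these lists had a member that passed over all genes or adjusted over the list alone.

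Lists that follow dissection and handling gave the following values. The 20 immediate early and heat shock genes were higher as a list (mean 0.18, adjusted p = 0.046, camera with a preset correlation, adjusted p = 0.90 with an estimated correlation). This mean was -0.08 without vehicle replicate 1 (adjusted p = 0.32) and 0.45 without vehicle replicate 2 (4.23e-06), and the call was lost without diosmetin replicate 1 (adjusted p = 0.25), with no filter on low values, no variance trend or array quality weights. Hspa1a, an inducible heat shock protein with the near-identical copy Hspa1b, was at 5.49 ± 0.974 (SD, n = 3) against 3.46 ± 0.303 FPKM (n = 2). Circadian genes (18, mean -0.01, adjusted p = 0.23), sex-dependent kidney genes (14, -0.13, 0.074), adipocyte markers (5, -0.20, 0.10) and red blood cell markers (9, -0.08, 0.90) did not pass. The circadian list joins genes of opposite phase, and the sex-dependent list joins genes higher in males with genes higher in females. Opposite shifts can cancel in such a mean, so these 2 lists decide nothing about clock phase or sex-hormone state. The adipocyte list includes Pck1, also a proximal tubule marker, with a log2 difference of -0.61, and 2 of its 5 members were higher. The circadian mean was 0.13 without vehicle replicate 1, 0.03 without diosmetin replicate 3 and -0.16 without vehicle replicate 2 (adjusted p = 2.51e-04), and the red blood cell mean -0.47 without vehicle replicate 1, 0.31 without vehicle replicate 2 and 0.27 without diosmetin replicate 1. The mean of sex-dependent genes was -0.18 without diosmetin replicate 2 (adjusted p = 0.036), -0.19 without vehicle replicate 1 (0.19), -0.04 without diosmetin replicate 1 (0.14) and -0.06 without vehicle replicate 2 (0.12). Neutrophil, adrenal and skeletal muscle markers had 4 measured genes each and were not tested. The mean FPKM of the 16 neutrophil markers in the table was 0.134 and 0.307 under vehicle and 0.481, 0.537 and 0.457 under diosmetin. Each diosmetin library thus lay above both vehicle libraries. That list includes Lcn2, also a kidney injury gene, at 0.672 and 1.09 FPKM under vehicle and 1.78, 4.85 and 1.30 under diosmetin. Diosmetin replicate 2 lay above vehicle replicate 2 only through that gene. Means ran from 1.55 to 1.79 FPKM over libraries for adrenal markers and from 8.24 to 10.4 for skeletal muscle markers. Most of the latter mean, taken over 13 genes, came from Pvalb, which is also a distal tubule marker. It was at 114 and 104 FPKM under vehicle and at 112, 132 and 133 under diosmetin. The 4 sex-linked genes used here had a mean of 0.013 FPKM or less in every library.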

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

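The numbers of genes at an unadjusted p under 0.05, of collecting duct and T and NK cell members passing adjusted over the list alone, and of lists passing in other splits were added after the data were seen, and all other results and alternatives here were planned. In each of the 13 alternatives to the gene test 0 genes passed with limma, with a smallest adjusted p from 0.1998 (without vehicle replicate 2) to 1.0 (without diosmetin replicate 2). At an unadjusted p under 0.05 the number was 847 and ran from 386 without diosmetin replicate 2 to 1463 without vehicle replicate 2. The higher share among such genes was 50.5% with median-of-ratios scaling and 57.0% with quantile normalization against 73.4%. Without vehicle replicate 1 most such genes were lower, while over all tested genes 56.0% were higher, against 63.9% with all libraries. Leaving out a vehicle library leaves a single vehicle sample, assumed to vary like the diosmetin samples, and the smallest exact p is then 0.25. Since the deposited values used here are not counts, the planned count models (edgeR and DESeq2) were not run. Depth limits mainly the low genes, since an FPKM of 0.5 in a 2 kb transcript rested on 38.4 to 48.6 fragments.

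Of the 28 lists, 8 passed camera, and between 6 (without diosmetin replicate 3) and 15 (without vehicle replicate 1, and as many without vehicle replicate 2) when a library was left out, but 0 with an estimated correlation and 0 with fry. Of the 9 other splits of the libraries, 7 gave at least 8. Of the 20 lists that did not pass, 16 had a mean that turned sign without at least 1 library. The adjusted p with an estimated correlation was 0.9012 for the interferon-stimulated, interferon gamma-induced, podocyte and immediate early lists, 0.970 for macrophage markers, 0.792 for proximal tubule and for loop of Henle and distal tubule markers, and 0.541 for collecting duct markers. With fry it was 0.939 for the interferon-stimulated, interferon gamma-induced, podocyte and immediate early lists, 0.983 for macrophage markers, 0.774 for proximal tubule markers, 0.656 for loop of Henle and distal tubule markers and 0.178 for collecting duct markers. The collecting duct, proximal tubule and loop of Henle lists kept their direction and passed camera in all 13 alternatives with the preset correlation. The number of collecting duct members passing adjusted over the list alone was 14, then 8 with median-of-ratios scaling, and from 9 (without vehicle replicate 1) to 13 (without vehicle replicate 2) with a library left out. That of T and NK cell members was 1 and ran from 0 to 2.

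Mean log2 differences without vehicle replicate 1 and without vehicle replicate 2 were -0.58 and 0.17 for interferon-stimulated genes and for their score, -0.49 and 0.22 for interferon gamma-induced genes, -0.72 and 0.58 for macrophage markers, -0.36 and 0.18 for podocyte markers, -0.083 and 0.45 for immediate early genes, and -0.010 and 0.094 for phosphatidylethanolamine genes and their score. The cause was not tested beyond the single library left out. The macrophage list lost its call with a pseudocount of 0.1 (-0.059), no filter on low values (-0.048), median-of-ratios scaling (-0.11) and quantile normalization (-0.12). The podocyte list lost it with no filter on low values (-0.091) and median-of-ratios scaling (-0.14), and the immediate early list with no filter on low values (0.17), no variance trend (0.18) and array quality weights (0.17). The cause of these losses was not tested. With median-of-ratios scaling the phosphatidylethanolamine list and its score turned to -0.0068, Etnk1 to -0.027, Etnk2 to -0.026 and Havcr1 to -0.039. With quantile normalization Etnk2 turned to -0.023 and Havcr1 to -0.038, and Oas2 turned to 0.013 with a pseudocount of 0.1 and to 0.0072 on rescaling to TPM.

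Of 104 named genes 70 kept their sign in the alternatives run and 34 did not, 30 of them only when a library was left out. From without vehicle replicate 1 to without vehicle replicate 2, log2 differences were -1.53 to 0.074 for Ifit3, -1.04 to 0.11 for Ifit1, -1.34 to 0.565 for Irf7, -0.32 to 0.29 for Oas2, -0.11 to 0.045 for Ifnar1, -1.56 to 0.30 for Cxcl10 and -0.83 to 0.045 for Irf5. They were -0.0050 to 0.57 for H2-Aa, -0.11 to 0.64 for Cd74, -1.08 to 0.19 for C3, -1.23 to 0.032 for Tnf, -1.23 to 0.32 for Vcam1, -1.16 to 0.33 for Ccl5, -1.02 to 0.30 for Cd22, -1.59 to 0.69 for Cybb, -0.46 to 1.24 for C1qa and -1.045 to 0.29 for Fcgr4. They were -0.011 to 1.28 for Acot1, -0.074 to 1.06 for Cyp4a14, -0.25 to 1.25 for Col1a1, -0.047 to 0.55 for Mcm6, -0.094 to 0.59 for Top2a, -0.065 to 0.51 for Mcm5, -0.93 to 0.38 for Cdkn1c, -0.235 to 0.82 for Gja5, -0.93 to 0.016 for Hbb-bs and -0.14 to 0.10 for Pisd. From without vehicle replicate 2 to without vehicle replicate 1 they were -0.59 to 0.042 for Dbp, -0.72 to 0.19 for Ciart and -0.037 to 0.15 for Pcyt2. With a library left out Etnk1 ranged from -0.0051 to 0.063, Etnk2 from -0.10 to 0.15, Cyp1b1 from -0.049 to 0.18 and Havcr1 from -0.30 to 0.32, with the lowest value without vehicle replicate 1 for Etnk1 and without diosmetin replicate 2 for the others.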

Other observations

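The tests of KEGG pathways, of 1 vehicle library, of immune cell content, of the proximal tubule share, of intercalated against principal cells and of the splits for the collecting duct list were chosen after the results they bear on had been seen, as was leaving out each library in the pathways and marker groups given here. The ribosome pathway (129 genes) had 45 genes higher and 0 lower at an unadjusted p under 0.05, none of which passed over all genes, and a mean log2 difference of 0.14 and a median of 0.16 (adjusted p = 3.51e-10, camera with a preset correlation, adjusted p = 0.999 with an estimated correlation). Its centred score was -0.11 and -0.07 in the vehicle libraries and 0.04, 0.12 and 0.01 in the diosmetin libraries. Ribosomal protein genes have many processed pseudogenes among which the counting can divide fragments, and the median log2 difference over all genes was itself 0.04. The spliceosome (126 genes, mean 0.10), RNA transport (145, 0.10), ribosome biogenesis (69, 0.12) and mRNA surveillance (80, 0.08) pathways passed in the higher direction with the preset correlation, each with adjusted p = 0.999 with an estimated correlation. Aminoacyl-tRNA biosynthesis (44, 0.11) did not pass (adjusted p = 0.070), but did without diosmetin replicate 1 (0.14, adjusted p = 0.034) or vehicle replicate 1 (0.09, adjusted p = 0.035), with adjusted p = 0.999 with an estimated correlation over all libraries. The mRNA surveillance call was lost without diosmetin replicate 1 (adjusted p = 0.095), diosmetin replicate 2 (0.27) or vehicle replicate 2 (0.26).

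In the lower direction with the preset correlation passed, among others, the degradation of valine, leucine and isoleucine (47 genes, mean log2 difference -0.09, adjusted p = 1.07e-04), butanoate metabolism (23, -0.15, 2.94e-04) and histidine metabolism (18, -0.19, 3.49e-04), each with adjusted p = 0.999 with an estimated correlation. At an unadjusted p under 0.05 stood 2, 3 and 2 members that were lower, and the exact permutation p of the scores was 0.3, 0.2 and 0.1. Diosmetin replicate 1 lay with the vehicle libraries, at a centred score of 0.05 against 0.04 and 0.07 for valine, leucine and isoleucine and of 0.06 against 0.07 and 0.11 for butanoate. Without diosmetin replicate 2 these means were -0.04 and -0.08, and the histidine call was lost without vehicle replicate 1 (-0.13, adjusted p = 0.11). In all, 21 of 301 pathways passed with the preset correlation, 5 higher and 16 lower, and 0 with an estimated correlation. With a library left out the number was 10 (diosmetin replicate 2), 15 (diosmetin replicate 3), 38 (diosmetin replicate 1), 66 (vehicle replicate 1) and 100 (vehicle replicate 2). Most of the lower pathways not named here lost their call without diosmetin replicate 2. Among them were drug metabolism by cytochrome P450 (mean -0.04, adjusted p = 0.59, camera) and pentose and glucuronate interconversions (-0.06, 0.54). Without vehicle replicate 1 the means of these pathways were -0.0037 and 0.0078. The ribosome, spliceosome, RNA transport and ribosome biogenesis pathways kept their call without diosmetin replicate 2. The KEGG pathway of collecting duct acid secretion (25 genes, mean 0.13) did not pass (adjusted p = 0.056).

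The interferon-stimulated list was lower under diosmetin by a mean log2 difference of -0.21, but this difference rests on vehicle replicate 2, since the mean without it was 0.17. Immune cell content could account for the high values of that library, whose macrophage score was also the highest. If scores followed in proportion, diosmetin replicate 1, whose macrophage score lay 0.57 above the mean of vehicle replicate 1 and diosmetin replicates 2 and 3, would have an interferon-stimulated score 0.35 above them, and it lay at -0.0086 (SE 0.026 over genes). That lies below the proportional value, but a single library excludes nothing and immune cell content stays open. Whether vehicle replicate 2 or vehicle replicate 1 is nearer to the usual untreated kidney cannot be read from 2 libraries, so an effect of diosmetin on interferon signalling stays open.

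The collecting duct list was higher by 0.32. A lower share of proximal tubule would raise markers of all other cells alike, and it stays open: the collecting duct mean exceeded that of podocyte, endothelial and mesangial markers (0.02) by 0.31 ± 0.054 (SE over genes, which are not independent), by 0.16 without vehicle replicate 2 and by 0.46 without vehicle replicate 1, but it exceeded that of loop of Henle and distal tubule markers (0.22) by 0.10 ± 0.054 and, without vehicle replicate 1 or diosmetin replicate 1, by 0.020 or 0.025. More medulla in the diosmetin pieces stays open too, since 5 medullary genes had a mean of 0.16 ± 0.074 (SE), short of the 0.2 set beforehand, with 0.26 without vehicle replicate 2, 0.29 without diosmetin replicate 1, 0.058 without vehicle replicate 1 and 0.062 without diosmetin replicate 2. Intercalated cell members had a mean of 0.41 and principal cell members of 0.20, a difference of 0.21 that was 0.32 without vehicle replicate 1 and 0.10 without vehicle replicate 2, and the permutation p of 0.0146 over the members decides nothing, because intercalated cell genes had been seen to lead and members of 1 list vary together. In 1 of the 10 splits, the labelled one, the mean was as large (highest other 0.23), and 10 splits are too few for a share under 0.05.

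More genes were higher than lower at an unadjusted p under 0.05 (73.4% of 847). Without vehicle replicate 1 most genes at that level were lower, so the direction among them rests on that library. Over all tested genes 63.9% were higher, and 56.0% without vehicle replicate 1, so there the direction did not turn. Library scaling stays open. The share at an unadjusted p under 0.05 was 50.5% with median-of-ratios scaling, but that scaling centres all genes (median log2 difference from 0.04 to -0.0040). A near-even share therefore follows from it and decides nothing. As for the number itself, 3 of the 10 splits gave as many genes, the highest other being 1362, when diosmetin replicates 2 and 3 were set against the rest, and 10 splits are too few for a share under 0.05. The split of vehicle replicate 1 and diosmetin replicate 1 against the rest gave 1273.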
